A study of Arabidopsis thaliana with 18 samples.

How the data were processed

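Expression was measured with Affymetrix arrays hybridised with biotin-labelled total RNA from whole Arabidopsis thaliana Col-0 seedlings, 5 days old. Each sample was a separately sown flask of about 40 seeds in 25 ml of liquid medium, grown at 21 °C. Wild type was compared with a 35S::GR-HDG1 line, in which the transcription factor HDG1 is fused to the hormone-binding part of the glucocorticoid receptor. The fusion enters the nucleus when dexamethasone (DEX) is given. Samples were treated for 8 h with 10 µM DEX, with 10 µM cycloheximide (CHX), which blocks protein synthesis, or with both. This gave 6 groups of 3 arrays, 18 in all. The labels do not say whether the 3 samples of a group came from independent experiments, so p-values measure the spread between these samples. No group received neither compound, and the line was not measured without DEX in the absence of CHX.

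The deposited values were log2 expression signals per transcript cluster, made per the labels by the authors with RMA (background correction, quantile normalization and summarization) in the oligo package, of which no version is given. The values lay between 1.41 and 14.26, and array medians between 4.67 and 5.13. The number of arrays limits the precision of each value. The genome build and the array annotation used by the authors are not stated, so no positions are given.

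The table held 38408 rows. The annotation listed 17481 of them (45.5%), of which 16722 named a single gene and 759 named several. Entrez identifiers matched 16574 of the single-gene rows to the reference table. This left 16548 named genes, of which 148 had several rows and were represented by the row with the highest mean. The planned rule was to test rows with a gene if at least 80% of rows had one, and otherwise all rows, so all 38408 rows were tested. A test of all rows, also set out beforehand, is therefore the same as the analysis reported. Of the rows, 7132 were identical to another row on all 18 arrays, which left 32879 distinct profiles.

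A single limma fit (limma 3.58.1, R 4.3.3) of 6 group means over the 18 arrays had 12 residual degrees of freedom, a prior of 3.12 degrees of freedom and a prior SD of 0.221 log2. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a row was called at an adjusted p under 0.05. Every adjusted p for a gene comes from this limma fit, every SE is from the fit, and every SD is over the 3 arrays of a group. The 8 comparisons were GR-HDG1 against wild type under DEX, under CHX and DEX, and under CHX alone; CHX and DEX against CHX in each genotype; the difference of these DEX effects between genotypes; CHX and DEX against DEX in wild type; and the line effect under DEX minus the line effect under CHX and DEX. Calls shared between comparisons were tested with a one-sided Fisher's exact test.

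The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took, for each of the line comparisons with DEX, the 10 highest and 10 lowest log2 changes among called genes whose 3 arrays in one group all lay above the 3 of the other. It took 4 and 4 in each other comparison, the genes called in both line comparisons with DEX, and up to 4 members of each list. HDG1 was to come first, but the tables used here name no row for it, so the label of the line could not be checked on its own transcript. Genes outside the rule are said to have been chosen after their values were seen.

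Of the 31 planned lists (24 of pathways and families, 7 of markers of other cell types) with 529 entries, 63 entries had a named row. Of these lists, 9 had at least 3 members and were tested, and 8 had none. A further 30 lists were made from the gene symbols of the annotation after it was seen but before any fold change was computed. Lists were tested over named genes with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Fry asks whether the members of a list move, on balance, in the same direction, without comparing them with other genes. P-values were adjusted over 45 tests of planned lists and 150 of added lists in 5 comparisons, and over 9 and 30 tests in the CHX comparison, whose list tests were added later. The list median and mean differed in sign in 8 of the 45 and 18 of the 150 tests.

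Replicate numbers were tested for pairing by correlating, between groups, the deviations of arrays from their group mean. Same-numbered DEX arrays of the 2 genotypes gave 0.42, 0.22 and 0.17, all above 0.1. By the rule set beforehand the numbers were therefore taken to pair the DEX samples. The fit of group means behind the reported gene values did not use this pairing, and the replicate number entered as a block in other settings. Replicates 2 and 3 crossed between the genotypes gave 0.15 and 0.17, so nothing sets the pairs numbered 2 and 3 apart. With 3 arrays per group, a deviation shared by the replicate 1 arrays moves replicates 2 and 3 together the other way. The 3 values are thus not separate support for pairing. Same-numbered arrays gave 0.07, -0.08 and -0.12 under CHX, and -0.03, -0.21 and -0.09 under CHX and DEX. In tests on simulated data with the spread of these arrays, the comparison under DEX recovered 0% of 200 changed rows at a true change of 0.5 log2, 52% at 1 log2 and 92% at 2 log2. Of the calls at 1 and 2 log2, 2.8% and 8% were false. The difference of DEX effects recovered 0%, 18% and 75.5%. These shares hold for 200 changed rows. In the data 844 rows were called under DEX, among them the gene NRPC2 at -0.47, so the 0% is not a detection limit there. Camera called a list of 20 genes shifted by 0.5 log2, and 4.5% of 200 unshifted lists fell under an unadjusted 0.05. The simulated rows varied independently and the lists were drawn at random. This test therefore cannot show how camera behaves on lists of genes that vary together.

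Other settings set out beforehand were quantile normalization once more, centring of each array on its median, leaving out rows under the 25th or 50th percentile of mean signal, a prior with an intensity trend, array quality weights, a fit on the compared groups alone, the replicate number as a block, and leaving out each array in turn. Settings chosen after seeing the data were rows with a gene alone, identical rows tested once, the replicate block in the DEX arrays alone, leaving out both DEX arrays numbered 1, and leaving STN1, a telomere gene by its locus, out of the list of nuclear-encoded photosynthesis. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.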

Results

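The data were 18 arrays of seedling RNA in 6 groups of 3: wild type and GR-HDG1 seedlings, each after 8 h with DEX, with CHX, or with both. Cycloheximide separated the arrays. The first principal component, with 79.6% of the variance, parted arrays with CHX from arrays without it, and the next components held 3.2% and 2.3%. The median SD within a group ran from 0.178 log2 in wild type with DEX to 0.229 in GR-HDG1 with CHX and DEX. Replicate 2 of that last group had the lowest mean correlation with the other arrays of its group, 0.9731.

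GR-HDG1 seedlings were first compared with wild type under DEX alone. This comparison holds what HDG1 activity changes, directly or through newly made proteins. It also holds any difference of the line that does not need DEX. The line was not measured without DEX in the absence of CHX, so these parts cannot be told apart here. AT3G22142, of the lipid transfer and seed storage inhibitor family, fell 11.1-fold. Its log2 signal was 11.20 ± 0.14 (SD, n = 3) in wild type and 7.72 ± 0.29 in GR-HDG1, a change of -3.47 (SE 0.18, adjusted p = 7.3e-08). RR16, a type-A response regulator of cytokinin signalling, fell 3.92-fold, from 5.06 ± 0.10 to 3.09 ± 0.12 (log2 change -1.97, SE 0.13, adjusted p = 1.09e-06). CLE41, which encodes the TDIF peptide that acts on vascular stem cells, fell 3.80-fold, from 7.70 ± 0.14 to 5.78 ± 0.25 (log2 change -1.93, SE 0.15, adjusted p = 1.05e-05). XTH33, a xyloglucan endotransglucosylase of the cell wall, rose 3.36-fold, from 7.20 ± 0.31 to 8.95 ± 0.14 (log2 change 1.75, SE 0.22, adjusted p = 0.000764).

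The 10 named genes that rose by the widest margin under the rule lay between 1.52 and 1.90 log2. Beside XTH33 they were AT2G34620 of the mTERF family (1.90), QQS, an orphan gene linked to starch content (1.79), AT4G09890 (1.79), AT1G07710 of the ankyrin repeat family (1.73), AT5G44005 (1.62), SCPL32 (1.56), AT1G12845 (1.53), the thionin THI2.2 (1.53) and AT5G03120 (1.52). Beside AT3G22142 the 10 that fell were AT3G15680, a zinc finger gene (-2.71), AT4G12500 of the same family as AT3G22142 (-2.46), AT2G43620 of the chitinase family (-2.44), the glutaredoxin AT4G15660 (-2.22), AT4G36850 (-2.19), AT3G53100 of the GDSL lipase family (-2.16), AT3G11930 of the universal stress protein family (-2.12), AT3G24230 of the pectate lyase family (-2.11) and the glutathione transferase GSTU20 (-2.04). By the rule that selected them, in each of these genes the 3 arrays of one genotype all lay above the 3 of the other. The calls of AT5G44005, THI2.2, AT5G03120, AT4G12500, AT4G15660 and AT3G11930 were lost in 3, 4, 5, 5, 5 and 3 of the 6 fits that left out an array, with adjusted p up to 0.0692, 0.0723, 0.142, 0.133, 0.152 and 0.0684. These highest values came without wild-type replicate 3 for AT5G44005, GR-HDG1 replicate 3 for THI2.2, wild-type replicate 2 for AT5G03120, AT4G15660 and AT3G11930, and GR-HDG1 replicate 2 for AT4G12500.

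In all, 844 of the 38408 rows were called, 345 higher and 499 lower in GR-HDG1, and 351 changed at least 2-fold. They included 393 named genes, 147 higher and 246 lower, and in all but 1 of them the arrays of the genotypes did not overlap. Non-overlap follows in large part from a call with 3 arrays per group, so it adds little to these calls. Over all rows, 18.7% did not overlap, against 10% by chance. With the replicate number as a block the count was 667, of which 632 were among the 844, and with the block in the DEX arrays alone it was 1158. The count fell to 429 without wild-type replicate 2, 370 without wild-type replicate 3, 493 without GR-HDG1 replicate 2 and 507 without GR-HDG1 replicate 3, was 136 in a fit on the DEX arrays alone, and rose to 2414 with array quality weights. Of the called genes, 58 were followed through each setting. The fit on the DEX arrays alone ended 38 of these calls, and 16 were kept in every setting. XTH33, RR16, CLE41 and AT3G22142 were among the 16, while EXPA8, XTH32 and IAA29, given below, were not.

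**Figure D1:**
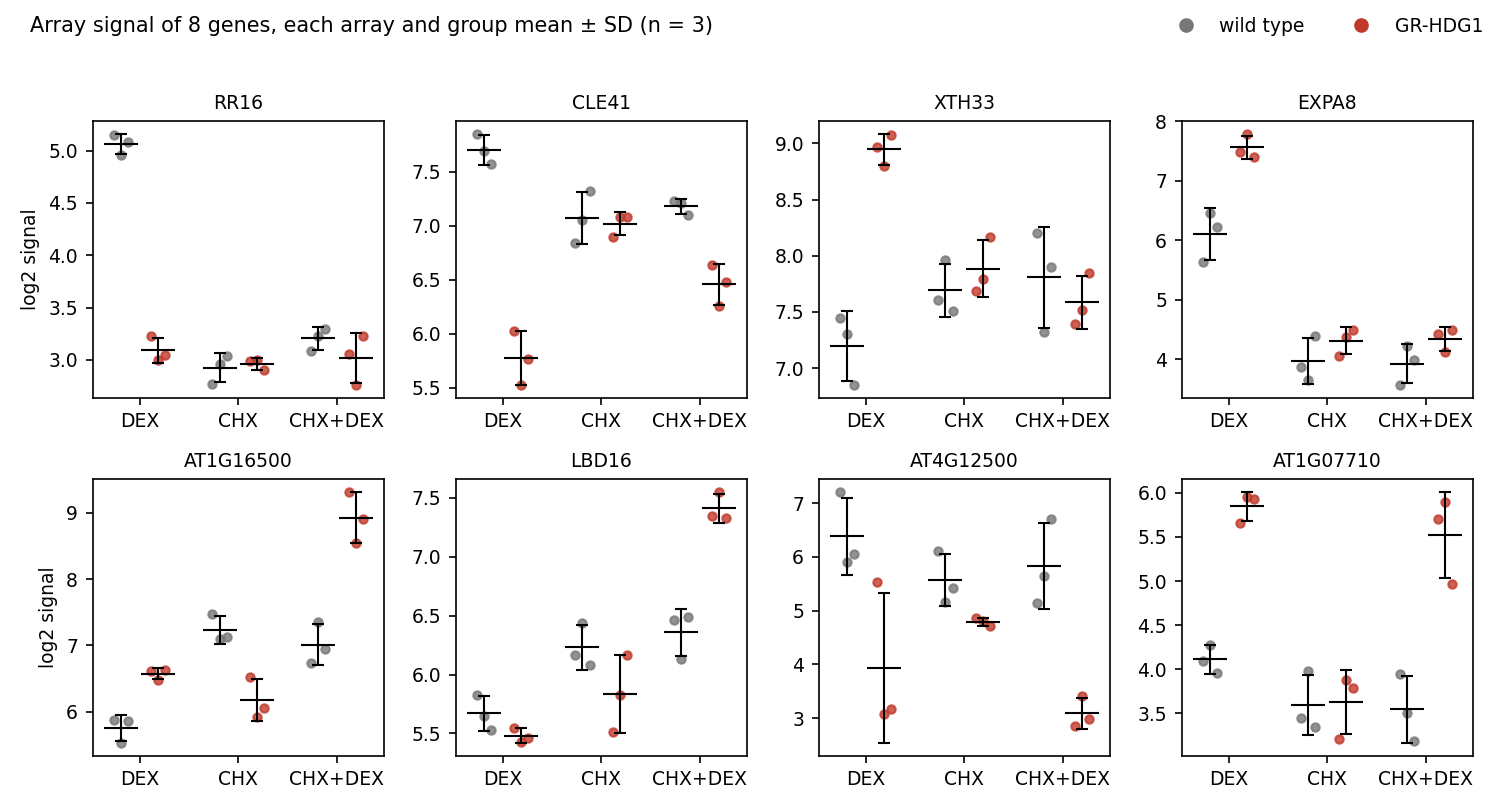
Array signal (log2) of 8 genes in each array (points) of wild type (grey) and GR-HDG1 (red) under DEX, CHX, or CHX and DEX, with group means and SD (black, n = 3). RR16 lay at 5.06 in wild type under DEX and near 3 in every other group, while AT1G16500 and LBD16 were highest in GR-HDG1 with CHX and DEX, and AT1G07710 was higher in GR-HDG1 in both treatments that held DEX.

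Of the planned lists, cytokinin response had 2 measured members and both fell under DEX, RR16 and ARR15 (log2 change -1.06, SE 0.24, adjusted p = 0.0336); with 2 members it was not tested as a list. Both also passed when adjusted over the list alone. Alpha expansins and xyloglucan endotransglucosylases had 10 members, of which XTH33 and EXPA8, a wall-loosening expansin (1.45, SE 0.24, adjusted p = 0.00489), rose and 8 did not pass; the members EXPA4 (-0.63) and XTH16 (0.70) had adjusted p of 0.213 and 0.32. Adjusted over the list alone, 2 rose and 1 fell. The median of that list was -0.24 and its mean 0.14, and its camera test gave adjusted p = 0.921. In the auxin response list, 1 of 8 members rose, the repressor gene IAA29 (1.40, SE 0.22, adjusted p = 0.00374), or 2 when adjusted over the list alone; GH3.3 stood at 0.76 (adjusted p = 0.176). In the stomatal lineage list, 1 of 4 members fell, SPCH, which starts the lineage (-1.33, SE 0.33, adjusted p = 0.0469), and STOMAGEN, a peptide gene that promotes stomata, stood at 0.72 (adjusted p = 0.0957); adjusted over the list alone 1 rose and 1 fell, and the median was 0.05 against a mean of -0.13. The calls of ARR15 and SPCH were lost in 5 and 4 of the 6 fits that left out an array, with adjusted p up to 0.139 and 0.185, both without wild-type replicate 3.

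The mitotic list had 3 measured members, the Aurora kinases AUR1 (-0.72, adjusted p = 0.0429), AUR3 (-0.53, adjusted p = 0.217) and AUR2 (-0.51, adjusted p = 0.511), of which 1 fell over all rows and 2 when adjusted over the list alone. Its camera test was the single call among the 45 planned tests (adjusted p = 0.0429), and adjusted p = 0.651 with an estimated correlation. The other tested lists had no called member under DEX: abscisic acid and water stress (4 members, adjusted p = 0.996), anthocyanin and flavonoid synthesis (3, 0.472), gibberellin (3, 0.996), shoot meristem and boundary (3, 0.73) and trichome and root hair patterning (3, 0.403); camera gave 0.403 for auxin response and 0.996 for the stomatal lineage. Lists with fewer than 3 members had no called member apart from cytokinin response. They included the cuticular wax gene AT4G13840 (0.58, adjusted p = 0.104), the DNA replication gene PRL (-0.49, adjusted p = 0.0683), both past 0.05 when adjusted over the list alone, and BBM of the AINTEGUMENTA-LIKE family (0.10, adjusted p = 0.965). The HD-ZIP class IV family and the lipid transfer protein list had no named member. Markers of other cell types with a named row were 2 of root hairs (median -0.09) and 2 of mesophyll photosynthesis (median 0.15), none of them called.

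Among the 30 lists made from the annotation, 5 shifted under DEX by camera, and none of the 5 with an estimated correlation (adjusted p = 0.587 for each). Cell division and chromosome segregation (28 members, median -0.26, adjusted p = 1.97e-05) had 3 members that fell, the topoisomerase TOPII (-1.06, adjusted p = 0.0148), the INCENP-like WYR (-0.76, adjusted p = 0.0413) and AUR1, and 25 that did not pass. Nucleolar and ribosome assembly (14 members, median -0.33, adjusted p = 4.33e-06) had 3 that fell, the RNA polymerase I subunits NRPA1 (-0.61, adjusted p = 0.0151) and NRPA2 (-0.49, adjusted p = 0.0193) and the RNA polymerase III subunit NRPC2 (-0.47, adjusted p = 0.0491). Nuclear-encoded photosynthesis (27 members, median 0.34, adjusted p = 1.61e-07) had 2 that rose, the photosystem I gene PSAN (0.96, adjusted p = 0.0319) and PGRL1B (0.62, adjusted p = 0.0374); without STN1, a telomere gene listed by its symbol, the median was 0.36 and adjusted p = 2.99e-08 (0.569 with an estimated correlation). Autophagy (10 members, median 0.34, adjusted p = 0.00281) had 2 that rose, ATG8C (0.62, adjusted p = 0.0164) and ATG8F (0.58, adjusted p = 0.0296). The cytokinin response regulators (8 members, median -0.10, mean -0.41, adjusted p = 0.0466) had RR16 and ARR15 as their 2 that fell. By fry, autophagy, nucleolar assembly and response regulators passed (adjusted p = 0.0174 for each), and nuclear-encoded photosynthesis (0.152) and cell division (0.118) did not.

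Each of the member calls in these lists apart from RR16 was lost without at least 1 array. Adjusted p reached 0.0647 for TOPII, 0.196 for WYR, 0.203 for AUR1 and 0.0931 for NRPA2 without wild-type replicate 3, 0.0575 for NRPA1 without GR-HDG1 replicate 1, and 0.155 for NRPC2, 0.114 for PSAN, 0.156 for PGRL1B, 0.0813 for ATG8C and 0.13 for ATG8F without wild-type replicate 2. The list of xyloglucan endotransglucosylases (9 members, adjusted p = 0.246) held XTH33 and XTH32 (1.18, SE 0.19, adjusted p = 0.00394) as members that rose. The SWEET sugar transporters (14 members, adjusted p = 0.105) held SWEET13 (-0.99, adjusted p = 0.0088) and SWEET10 (-0.81, adjusted p = 0.0115) as members that fell; the call of SWEET10 was lost without wild-type replicate 3 (adjusted p = 0.0647) and without GR-HDG1 replicate 3 (0.0556).

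**Figure D2:**
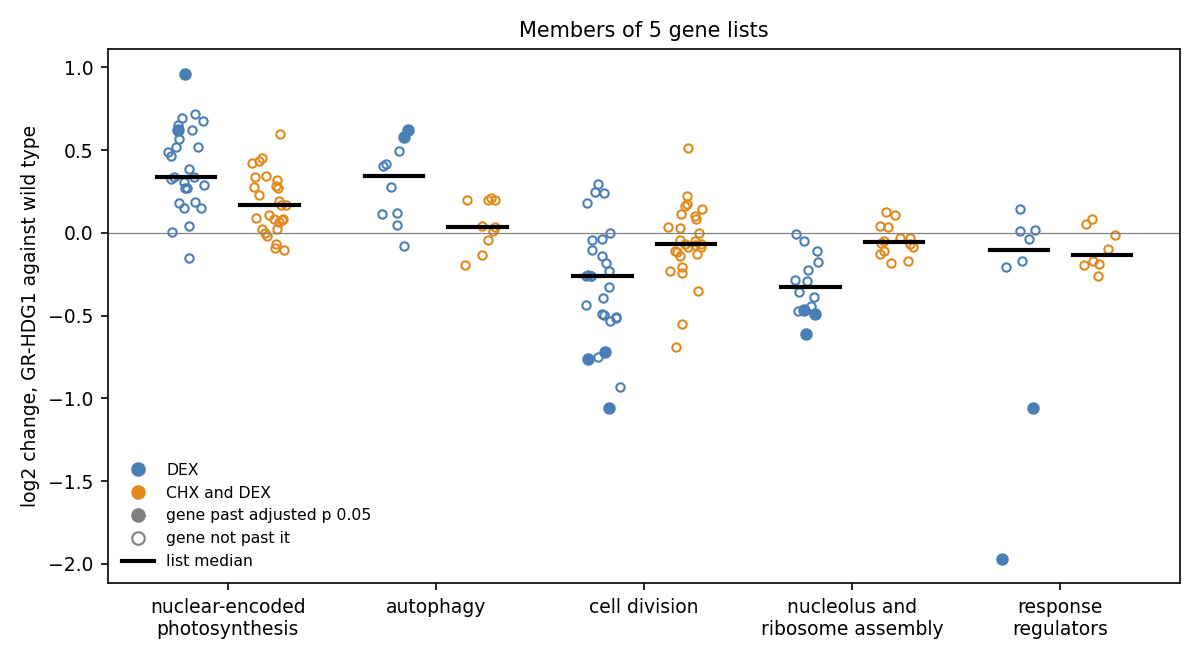
Log2 change of GR-HDG1 against wild type for the members of 5 gene lists under DEX (blue) and under CHX and DEX (orange); filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians. Under DEX the medians were 0.34 for photosynthesis and autophagy, -0.26 for cell division, -0.33 for nucleolar and ribosome assembly and -0.10 for response regulators.

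The same comparison with CHX and DEX asks which genes change when proteins can hardly be made. AT2G46150, of the late embryogenesis abundant family, rose 3.85-fold, from a log2 signal of 6.17 ± 0.18 (SD, n = 3) in wild type to 8.11 in GR-HDG1 (log2 change 1.95, SE 0.21, adjusted p = 0.000232). AT1G16500 rose 3.75-fold, from 7.01 ± 0.31 to 8.92 (1.91, SE 0.21, adjusted p = 0.000403), and AT3G04050, of the pyruvate kinase family, rose 3.32-fold (1.73, adjusted p = 0.000585). LBD16, which acts in the start of lateral roots, rose 2.07-fold (1.05, SE 0.16, adjusted p = 0.00839) and was the called member of the 8 in the auxin response list. AT5G50120 of the WD40 family fell 2.15-fold (-1.11, adjusted p = 0.000193), and AT5G36130 fell 5.90-fold (-2.56, SE 0.36, adjusted p = 0.00375). Under CHX alone, AT5G36130 was already lower in GR-HDG1 (6.74 against 7.73 in wild type), without being called. Of the 21 named genes that fell with CHX and DEX, 19 lay lower there.

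The other named genes that rose under CHX and DEX were AT5G12420 of the wax ester synthase family (2.33), AT1G78230 (2.25), AT1G07710 (1.97), AT5G01320 of the pyruvate decarboxylase family (1.71), AT1G79160 (1.56), the protein phosphatase AT5G26010 (1.44) and the AP2/ERF factor AT2G44940 (1.37). Those that fell were AT4G12500 (-2.75), AT3G50610 (-2.03), AT5G42146 (-1.37), AT4G22940 (-1.36), AT4G15430 (-1.23), AT5G04980 (-1.17), AT1G29100 (-1.07) and the glutaredoxin AT3G62960 (-1.04). By the rule that selected them, in each the arrays of the genotypes did not overlap. From the lists, the endoglucanase GH9B8 (1.08, adjusted p = 0.00492) and the carboxypeptidase scpl25 (0.79, adjusted p = 0.0124) rose and SWEET13 fell (-0.98, adjusted p = 0.0249). RR16 stood at -0.19 (adjusted p = 0.814), XTH33 at -0.22 (0.917), EXPA8 at 0.42 (0.737), TOPII at -0.08 (0.971), AUR1 at -0.35 (0.64) and CLE41 at -0.72 (0.0726). The signal of RR16 in wild type was 3.21 under CHX and DEX, close to its 3.09 in GR-HDG1 under DEX. How far a fall could have been seen there is open.

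Of the rows, 134 were called, 91 higher and 43 lower, with 99 at least 2-fold, and 52 of them were named genes (31 higher, 21 lower), all without overlap of the genotypes. As under DEX, non-overlap follows in large part from the call itself. Over all rows 10.8% did not overlap, against 10% by chance. The count fell to 60 without wild-type replicate 1, 84 without wild-type replicate 2, 88 without GR-HDG1 replicate 1 and 86 without GR-HDG1 replicate 2, the array with the lowest mean correlation, and to 3 in a fit on the arrays with CHX and DEX alone. Of these 52 genes, 29 (those given here or called in both line comparisons with DEX) were followed through each left-out array, and 12 of the 29 kept the call throughout: AT1G07710, AT2G46150, AT1G16500, AT3G04050, AT1G79160, AT5G26010, AT5G36130, AT5G42146, AT4G22940, AT5G50120, LBD16 and GH9B8. None of the 29 kept it in the fit on the compared groups alone. AT5G12420, AT1G78230 and AT4G12500 lost it in 3, 4 and 6 of the 6 fits, with adjusted p up to 0.066, 0.16 and 0.182 without wild-type replicates 1, 2 and 3. No planned list shifted by camera. Of the lists from the annotation, nuclear-encoded photosynthesis shifted upward (median 0.17, no called member, adjusted p = 0.00744), with adjusted p = 0.958 under an estimated correlation.

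Genes called in both line comparisons with DEX were 2 that rose, AT1G07710 (1.73 under DEX, 1.97 with CHX and DEX) and AT3G20380 (0.96 and 1.18), and 7 that fell. The 7 were AT4G12500 (-2.46 and -2.75), AT5G42146 (-1.37 and -1.37), the sugar transporter SWEET13 (-0.99 and -0.98), AT3G50650 (-0.90 and -0.87), AT4G01600 (-0.88 and -1.03), AT1G61660 (-0.71 and -0.83) and AT2G28810 (-0.69 and -0.77). Chance would give 0.28 and 0.31 named genes (one-sided Fisher's exact p = 0.0308 and 1.43e-08). Over all rows, 21 were higher in both and 17 lower in both, where 0.82 and 0.56 would fall together by chance (one-sided Fisher's exact p = 7.12e-24 and 2.01e-21), and 2 were called in opposite directions. With identical rows counted once, 13 were higher in both and 17 lower (one-sided Fisher's exact p = 1.95e-13 and 1.59e-20). Of the rows called in both, 9 (5 distinct profiles, 4 of them higher throughout) were also called under CHX alone, so part of the overlap is a difference of the line that does not need DEX. All 7 named genes that fell in both also had a lower mean in GR-HDG1 than in wild type under CHX alone, without being called there. The gaps were widest for AT4G12500 (4.79 in GR-HDG1 against 5.57 in wild type), AT2G28810 (4.59 against 5.17) and AT5G42146 (5.16 against 5.68). Of the 2 that rose, AT1G07710 stood at 3.63 against 3.59 and AT3G20380 at 3.71 against 3.77. The comparisons share no arrays, but both use 1 estimate of spread per row, taken over all 18 arrays. A row with a small estimate is more easily called in both, which the chance counts and Fisher's tests do not allow for. The number shared fell from 38 to 18 without wild-type CHX and DEX replicate 1, to 25 without its replicate 2, to 21 without wild-type DEX replicate 2, and to 3 in fits on the compared groups alone. AT1G07710 and AT5G42146 kept both calls whichever array was left out, but lost the call with CHX and DEX in the fit on those groups alone (adjusted p = 0.252 and 0.241), as did the other named genes shared.

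Of the 393 named genes called under DEX, 301 (76.6%) had the same sign under CHX and DEX, but with a median change of 0.12 log2 in the direction of the call, against 0.87 under DEX. Under CHX alone, where the fusion was not activated, 262 of the same 393 (66.7%) also had the sign of the call, with a median of 0.06. Of the 52 called under CHX and DEX, 39 (75%) had the same sign under DEX. Under CHX alone, 11 of the 31 genes that rose (35.5%) and 19 of the 21 that fell (90.5%, median 0.26 in the direction of the call) had the sign of the call, so most genes that fell with CHX and DEX lay lower in the line without DEX as well, though none was called there.

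**Figure D3:**
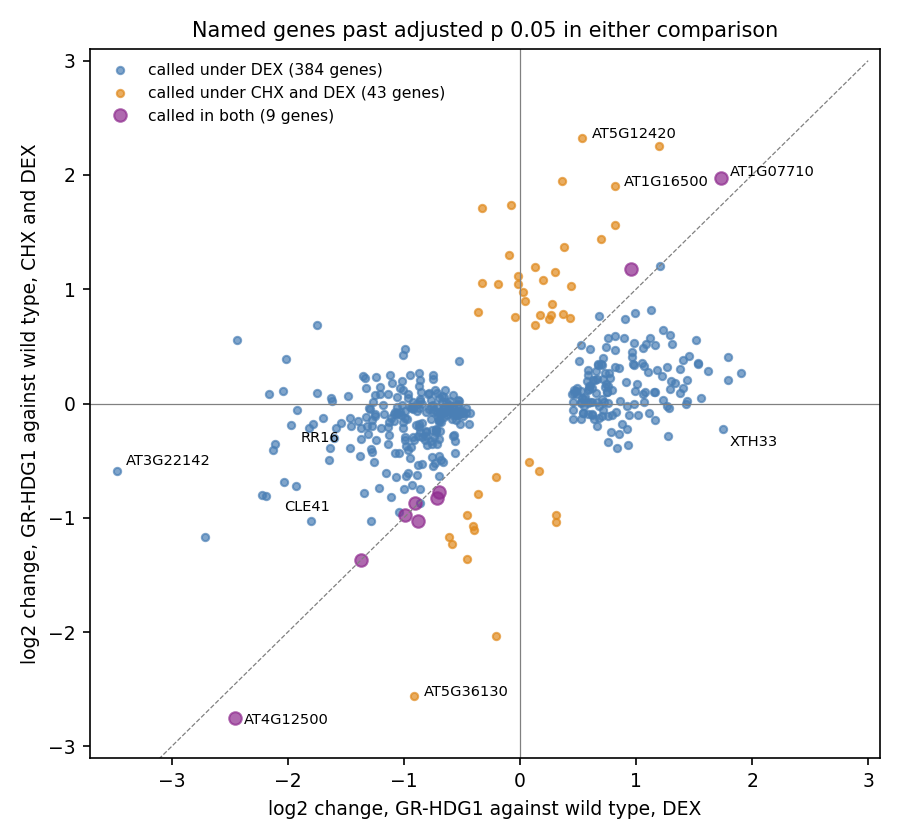
Log2 change of GR-HDG1 against wild type under DEX (horizontal) and under CHX and DEX (vertical) for named genes past an adjusted p of 0.05 in either. The dashed line marks equal change; the 9 genes called in both (purple) lie near it, and RR16 and XTH33 lie near 0 on the vertical axis.

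The difference between these line effects was tested directly, as the effect under DEX minus that under CHX and DEX. CLE41, whose wild-type signal with CHX and DEX was 7.18, fell further under DEX, by a difference of -1.21 log2 (adjusted p = 0.0372). XTH33 was higher in GR-HDG1 under DEX but not with CHX and DEX (difference 1.97, SE 0.32, adjusted p = 0.0158). The same held for AT1G52100 (1.43, adjusted p = 0.0407) and AT3G28310 (1.30, adjusted p = 0.0407). In wild type, AT1G52100 had a signal of 6.94 under DEX and 2.91 with CHX and DEX. Its difference therefore does not by itself show that HDG1 acts on it less when CHX is present. AT3G62960, lower with CHX and DEX, differed by 1.34 (adjusted p = 0.0457). LBD16, higher with CHX and DEX, differed by -1.24 (adjusted p = 0.0414).

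Another 6 genes with a negative difference had a lower wild-type signal with CHX to begin with. AT3G22142 (-2.89, adjusted p = 0.000138) and AT2G43620 (-3.0, adjusted p = 0.0131) had wild-type signals of 7.69 and 6.13 with CHX and DEX, no higher than the 7.72 and 6.48 of GR-HDG1 under DEX. RR16 (-1.78, adjusted p = 0.000376), the dirigent-like AT1G58170 (-2.41, adjusted p = 0.00422), GSTU20 (-2.15, adjusted p = 0.0066) and AT3G53100 (-2.24, adjusted p = 0.0407) had wild-type signals of 3.21, 3.31, 4.12 and 4.34 there, below the median of every array. The lowest signal that the probes of each gene can give is not known, so how far a fall could have been seen in these 4 genes is open. The differences of all 6 genes do not by themselves show that HDG1 acts on them less when CHX is present.

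This difference was called in 84 rows, 15 positive and 69 negative, 33 of them named genes, and 80 were at least 2-fold. AT3G22142, RR16, AT1G58170 and GSTU20 kept the call whichever of the 12 arrays was left out. XTH33 lost it without wild-type DEX replicate 3 and without GR-HDG1 CHX and DEX replicate 1 (adjusted p up to 0.0533), and AT2G43620 without wild-type DEX replicate 3 (0.0506). AT3G53100, CLE41, AT1G52100, AT3G62960, AT3G28310 and LBD16 lost it in 8, 10, 10, 9, 9 and 12 of the 12 fits, with adjusted p up to 0.107, 0.0956, 0.106, 0.122, 0.104 and 0.115. These highest values came without wild-type DEX replicate 2 for AT3G53100, CLE41 and AT1G52100, wild-type DEX replicate 3 for AT3G28310, and wild-type CHX and DEX replicate 1 for AT3G62960 and replicate 2 for LBD16. Without each array that moved the count past 1.5 times it was 36 (wild-type DEX replicate 3), 47 (wild-type DEX replicate 2), 45 (GR-HDG1 DEX replicate 2), 51, 51 and 53 (wild-type CHX and DEX replicates 1, 2 and 3) and 46, 55 and 55 (GR-HDG1 CHX and DEX replicates 1, 2 and 3), and in a fit on the compared groups alone it was 26. From the lists made from the annotation, cell division (median -0.29, adjusted p = 0.00278) and nucleolar and ribosome assembly (median -0.26, adjusted p = 0.000667) shifted by camera with no called member, with adjusted p = 0.712 and 0.587 under an estimated correlation.

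Adding DEX to CHX in GR-HDG1 seedlings raised AT2G01023 by 4.01 log2 (adjusted p = 0.000159), AT1G78230 by 3.21 (adjusted p = 0.00264), AT1G16500 by 2.75 (adjusted p = 5.33e-05) and AT2G46150 by 2.53 (adjusted p = 5.57e-05). AT5G52740 (-2.00), AT4G36850 (-1.69), AT1G16230 (-1.24) and AT3G43430 (-1.13) fell. The calls of AT5G52740 and AT4G36850 were lost in 3 and 4 of the 6 fits that left out an array, with adjusted p up to 0.0846 and 0.154, both without GR-HDG1 CHX replicate 1, and the other 6 genes kept theirs. In wild type, adding DEX to CHX raised AT2G01023 by 3.77 log2 (adjusted p = 0.00241), so this gene responded to DEX without the transgene. The line gave 206 called rows (139 higher, 67 lower; 74 named genes) and wild type 8, all higher, with AT2G01023 as the named gene. At an unadjusted limma p under 0.05 the counts were 3773 and 2174 (9.8% and 5.7% of rows), where chance alone would give a share of 0.05. Of the 74 named genes, 49 (66.2%) had the same sign in wild type. The count in the line was 99, 101 and 123 without GR-HDG1 CHX replicates 1, 2 and 3 and 122 without GR-HDG1 CHX and DEX replicate 2; the count of 8 in wild type fell to 3 or fewer without CHX replicates 1 or 2 or CHX and DEX replicates 1 or 3.

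The DEX effect in GR-HDG1 minus that in wild type gives the part of the DEX response that differs between the genotypes, with CHX present throughout. AT1G16500 rose more in GR-HDG1 by 2.97 log2 (SE 0.30, adjusted p = 0.00208): its signal was 7.23 ± 0.21 (SD, n = 3) and 7.01 ± 0.31 in wild type without and with DEX, and 6.17 ± 0.32 and 8.92 in GR-HDG1. AT2G46150 (2.29, adjusted p = 0.0116), AT1G79160 (2.22, adjusted p = 0.0116), AT5G37470 (1.58, adjusted p = 0.0213), LBD16 (1.44, adjusted p = 0.0417) and scpl25 (1.16, adjusted p = 0.0356) also rose more. The remaining named genes among the 8 called, AT2G24140 (1.54, adjusted p = 0.0116) and AT5G02890 (1.39, adjusted p = 0.0184), were chosen after their values were seen. Under CHX without DEX, each of the 8 had a lower mean in GR-HDG1 than in wild type, though none was called there. Part of each difference thus lies in this lower start of the line. In all 14 rows were called, 13 positive and 1 negative. AT1G16500, AT2G46150, AT1G79160 and AT2G24140 kept the call whichever of the 12 arrays was left out. In a fit on the compared groups alone, 6 of the 8 named genes lost the call, all but AT1G16500 and AT2G46150. AT5G37470, LBD16, scpl25 and AT5G02890 lost it in 7, 11, 11 and 3 of the 12 fits, with adjusted p up to 0.0762 without wild-type CHX and DEX replicate 1, 0.133 without wild-type CHX replicate 2, and 0.116 and 0.0705 without GR-HDG1 CHX replicate 2. The count was 8 without wild-type CHX replicate 1, 23, 6 and 9 without GR-HDG1 CHX replicates 1, 2 and 3, 7 without wild-type CHX and DEX replicate 1, and 3 in a fit on the compared groups alone. With 75.5% of simulated changes of 2 log2 recovered but 18% at 1 log2, smaller effects were largely out of reach.

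Under CHX alone, GR-HDG1 and wild type differed in 22 rows, all higher in GR-HDG1, which held 14 distinct profiles. No named gene was among them by limma. Of all rows, 2330 (6.1%) had an unadjusted limma p under 0.05, near the share of 0.05 that chance alone would give. Of the 14 profiles, 11 were also called under CHX and DEX and 6 under DEX. Rows 13545469 and 13442096, which the annotation does not list and which were chosen after their values were seen, were higher in GR-HDG1 by 3.78 and 3.75 log2 under DEX, 6.90 and 6.76 under CHX and DEX, and 6.91 and 6.63 under CHX alone; what they measure is not known. The count was 53 without wild-type CHX replicate 3 and 14 in a fit on the CHX arrays alone. Among lists from the annotation, mitochondrion-encoded genes (median -0.13, adjusted p = 0.000138) and the chloroplast-encoded expression machinery (median -0.08, adjusted p = 0.0339) shifted by camera with no called member, with adjusted p = 0.589 and 0.958 under an estimated correlation.

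Cycloheximide itself changed wild-type seedlings far more than the line differed from wild type, with 20826 of 38408 rows called (54.2%) between CHX and DEX and DEX alone. AT3G54520, AT5G57510, AT5G55150 and AT2G38823 rose by 8.94, 8.91, 8.76 and 8.42 log2, and AT3G20370, AT3G16370, AT1G73600 and LCR69 fell by 6.07, 5.99, 5.97 and 5.76. The stress transcription factors WRKY41 (4.94), WRKY22 (3.79), WRKY6 (3.28) and WRKY29 (3.03) rose, 4 of the 7 listed (median 3.03, adjusted p = 0.0284, and adjusted p = 0.141 with an estimated correlation). Both members of the wound and immediate early list rose, WRKY6 and STZ (5.01). In the auxin response list 4 of 8 rose, GH3.3 (5.02), LBD29 (4.11), GH3.1 (4.01) and LBD16 (0.69), with adjusted p = 0.0514 for the list; 7 of the 8 were higher after median centring.

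Nuclear-encoded photosynthesis genes had a median change of -2.11 (27 members, 24 lower and 2 higher, adjusted p = 8.29e-09, and adjusted p = 0.221 with an estimated correlation), with NdhN at -3.1 and the chlorophyll synthesis gene CHLM at -3.22. By its locus, STN1 (2.9), counted among the 2 higher members, is a telomere gene and not a photosynthesis gene; without it the list had 24 lower and 1 higher of 26 members, a median of -2.16 and adjusted p = 3.55e-10 (0.168 with an estimated correlation). Cell division genes had a median of -1.03 (21 of 28 lower, adjusted p = 3.65e-07, and adjusted p = 0.141 with an estimated correlation), with the helicase RECQ4A at -3.34, TOPII at -2.87, AUR1 at -2.20 and the centromeric histone HTR12 at -1.76. The chloroplast-encoded expression machinery fell in 20 of 21 members (median -0.67, adjusted p = 9.93e-07, and adjusted p = 0.248 with an estimated correlation), with rps18 at -2.35 and rpoB at -1.60, but in 11 after quantile normalization and 11 after median centring, where the median was -0.32 and 1 member was higher. Mitochondrion-encoded genes fell in 12 of 17 as deposited (median -0.40, adjusted p = 0.00358, and adjusted p = 0.482 with an estimated correlation), in 7 after quantile normalization and in 1 after median centring (median -0.04), so that fall rested on the scaling. After centring, 22 members of nuclear-encoded photosynthesis and 20 of cell division were lower. The stomatal lineage genes SPCH (-2.52) and STOMAGEN (-1.45) fell under each scaling. FMA (-0.81) and MUTE (-0.64) fell as deposited, but not after median centring (-0.45 and -0.29); the list had adjusted p = 0.0514. RR16 (-1.86) and ARR15 (-1.10) fell as well. Chloroplast-encoded photosynthesis (43 members, 23 lower, adjusted p = 1.00e-04, or 0.555 with an estimated correlation) had a median of -0.26 that became 0.10 when each array was centred on its median, and serine carboxypeptidase-like genes (32 members, 13 lower, adjusted p = 0.0372, or 0.141) went from -0.11 to 0.25.

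The balance between rises and falls with CHX rested on the scaling. Of the called rows, 8565 were higher and 12261 lower as deposited (41.1% higher), but 48.2% were higher after quantile normalization and 64.3% after median centring. The median shift of a row from its deposited change was 0.13 and 0.36 log2 under these scalings. The changes above are as deposited unless said otherwise, where the median row changed by -0.06. Of the 9138 named genes called, 4896 were higher and 4242 lower, and 8882 did not overlap between groups.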

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

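The tests of how changes carry over between treatments were set out before their results were seen; how the other splits were made up was looked at after.

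The line effect differed between DEX and CHX with DEX in 84 rows, by a test of the difference itself. Of its 33 named genes, those followed here were XTH33 (1.97), AT1G52100 (1.43), AT3G62960 (1.34), AT3G28310 (1.30), AT2G43620 (-3.0), AT3G22142 (-2.89), AT1G58170 (-2.41), AT3G53100 (-2.24), GSTU20 (-2.15), RR16 (-1.78), CLE41 (-1.21) and LBD16 (-1.24), with YAB5 (1.29) and ATL4H (-1.34) chosen after their values were seen; with 1 array left out these last lost the call in 12 and 11 of 12 fits, with adjusted p up to 0.12 without GR-HDG1 CHX and DEX replicate 1 and 0.121 without wild-type CHX and DEX replicate 2. Among 100 ways to exchange genotype labels within DEX and within CHX and DEX, the real one included, 5 gave at least 84 rows and the highest other gave 302, so chance is not excluded by this count. The 4 others that reached 84 were among the 7 that left the DEX labels as they were, and the 92 that exchanged them gave at most 18; this follows from the construction, since the former keep the line effect under DEX, so it is a structure of the samples and does not bear on the difference between treatments. RR16, AT1G58170, GSTU20 and AT3G53100 were already low in wild type with CHX, so how far a fall could be seen there is open. AT3G22142, AT2G43620 and AT1G52100 also had a lower wild-type signal with CHX and DEX than under DEX. Their differences do not by themselves show that HDG1 acts on them less with CHX.

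The DEX effect with CHX present differed between GR-HDG1 and wild type in 14 rows, by a test of the difference itself. The 8 named genes were AT1G16500 (2.97), AT2G46150 (2.29), AT1G79160 (2.22), AT5G37470 (1.58), LBD16 (1.44) and scpl25 (1.16), with AT2G24140 (1.54) and AT5G02890 (1.39) chosen after their values were seen. Among 100 exchanges of genotype labels within CHX and within CHX and DEX, 5 gave at least 14 rows and the highest other gave 83, so chance is not excluded. The split with 83 exchanged all labels under CHX and DEX and none under CHX, so it sums the line effects of the treatments, a structure of the samples. Those with 26 and 15 exchanged 2 labels under CHX and none under CHX and DEX, so by construction they kept the line effect under CHX and DEX, while that with 30 exchanged 1 label in each treatment and is not explained.

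Far more rows were called between genotypes under DEX (844) than under CHX and DEX (134). A larger spread between arrays with CHX and DEX would hide changes but keep their size. In rows called with arrays held out, the median change was 0.98 log2 under DEX in the held-out arrays and 0.12 under CHX and DEX, a ratio of 0.126 (0.102 to 0.163 over 9 pairs of arrays), which argues against spread as the whole cause. A floor, with genes already low under CHX, is argued against as the whole cause by the rows lower in GR-HDG1 under DEX whose wild-type level was at least as high with CHX and DEX, where the ratio was 0.289 (0.94 and 0.27 log2; 0.214 to 0.364 over 9 pairs), but it stays open for dim genes such as RR16. A need for newly made protein downstream of HDG1 may account for the pattern, as a hypothesis from these same data, and an effect of CHX on transcription as a whole, with 54.2% of rows changed, stays open beside it. Line differences that do not need DEX may also be among the calls under DEX. They cannot be told apart, since the line was not measured without DEX in the absence of CHX.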

How the results depend on the processing

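The alternatives with rows that have a gene alone, identical rows tested once, the block in DEX arrays alone, both DEX arrays numbered 1 left out, and the photosynthesis list with STN1 left out were chosen after seeing the data. Where no reason is given, the cause was not tested. Counts are in the order DEX, CHX and DEX, CHX alone, DEX added in GR-HDG1, DEX added in wild type, their difference, CHX in wild type, and the difference of line effects (844, 134, 22, 206, 8, 14, 20826 and 84 rows). With fewer rows tested (those with a gene alone) they were 536, 60, 0, 97, 1, 9, 9957 and 43, with 12 shared calls in place of 38; the 0 is limma's count, as no named gene was called under CHX alone. Fits on the compared groups alone had fewer arrays to estimate spread. They gave 136, 3, 14, 38, 0 and 3 for the first 6 counts and 26 for the last, with 3 shared calls. Limma's 0 stands beside 2174 rows (5.7%) at an unadjusted p under 0.05 in the fit of all groups. That is near the share of 0.05 that chance alone would give. Array quality weights gave 2414 rows under DEX, 842 of them among the 844, and 150 for the difference of line effects. Identical rows tested once gave 12 rows under CHX alone and 4 for DEX in wild type, where the replicate block gave 5 and the block in DEX arrays alone 3. Without both DEX arrays numbered 1, 480 rows were called under DEX and 23 were shared. Each other alternative kept these counts within 1.5 times.

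With each array left out in turn, the counts ran from 370 to 709, 60 to 129, 18 to 53, 99 to 165, 1 to 10, 6 to 23, 18946 to 20054 and 36 to 85, and shared calls from 18 to 34. The lowest values came without wild-type DEX replicate 3 (370 and 36), wild-type CHX and DEX replicate 1 (60 and 18) and GR-HDG1 CHX replicate 1 (99) and replicate 2 (6).

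The single planned list called, of 45 tests, was 0 with an estimated correlation, fry, the replicate block, an intensity trend, array quality weights, the compared groups alone, or both DEX arrays numbered 1 left out. It was 2 without rows under the 25th percentile, and 0 to 1 with 1 array left out. Camera's unadjusted p was under 0.05 in 5 of the 45 tests. The 10 calls among 150 added list tests became 0 with an estimated correlation, 3 by fry and 16 with an intensity trend, and 7 to 12 with 1 array left out.

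Of 176 named gene values, 166 were past the threshold. Of these, 68 stayed past it in every setting run, 98 were lost in at least 1, and none turned direction. Most that stayed came from CHX in wild type, 43 of 45. The others were 16 of 58 under DEX, 0 of 29 under CHX and DEX and 3 of 11 for DEX added in GR-HDG1. For DEX added in wild type it was 0 of 1, for the difference of DEX effects 2 of 8, and for the difference of line effects 4 of 14. Of the 10 values not past the threshold, 3 passed in at least 1 setting. TOPII under CHX and DEX, not called (-0.08), turned to 0.05 without GR-HDG1 CHX and DEX replicate 1 (adjusted p = 0.98) and was -0.15 without replicate 2 of that group. Background may limit small changes in dim genes such as RR16 with CHX, but no background level was measured, so this is open.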

Other observations

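Further genes that changed in GR-HDG1 under DEX were chosen after their values were seen. ATC, a relative of the flowering repressor TFL1, fell 4.09-fold, from a log2 signal of 6.75 ± 0.35 (SD, n = 3) to 4.71 ± 0.20 (log2 change -2.03, adjusted p = 0.00107). SHI, a factor of gynoecium and leaf development, fell from 5.47 ± 0.09 to 4.56 ± 0.09 (-0.91, adjusted p = 0.00458). The subtilase ATSBT5.2 (-1.25, adjusted p = 0.00296) and the bacterial elongation factor receptor EFR (-0.87, adjusted p = 0.0101) fell as well. SFP2, of the sugar transporter family, rose from 6.87 ± 0.19 to 8.18 ± 0.06 (1.31, adjusted p = 0.00319). These 5 genes kept the call whichever of the 6 DEX arrays was left out. The auxin synthesis gene YUC6 fell (-1.0, adjusted p = 0.0171) and the leaf polarity gene YAB5 rose (0.93, adjusted p = 0.012), but YUC6 was lost in 4 of the 6 fits, with adjusted p up to 0.0802 without wild-type replicate 2, and YAB5 without wild-type replicate 3 (adjusted p = 0.0535).

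In the line with CHX, adding DEX raised further genes outside the rule, chosen after their values were seen. The homeodomain gene HAT2 rose by 0.94 log2 (adjusted p = 0.0302), the glucosinolate transporter GTR2 by 1.18 (adjusted p = 0.0183) and the peptide gene RALFL18 by 1.2 (adjusted p = 0.0183). With 1 array left out, adjusted p reached 0.122 for HAT2 without GR-HDG1 CHX replicate 1, 0.0784 for GTR2 without GR-HDG1 CHX replicate 3 and 0.0626 for RALFL18 without GR-HDG1 CHX and DEX replicate 1.

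The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. In each of these comparisons 1 of the 10, the real one, gave as many rows. The real count and the highest other were 844 and 5 under DEX, 134 and 33 under CHX and DEX, 22 and 1 under CHX alone, 206 and 10 for DEX added in GR-HDG1, 8 and 1 for DEX added in wild type, and 20826 and 0 for CHX in wild type. Under DEX, if replicate numbers are taken to pair the samples, 4 splits part all 3 pairs, and the highest other among them was 0. The 6 that part fewer gave at most 5.

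The replicate 1 arrays of both DEX groups deviated from their groups in the same way (correlation of deviations 0.42); both tests of this were chosen after it was seen. A day shared by a replicate number across treatments is argued against, since 0 of the 6 same-numbered pairs under CHX and under CHX and DEX passed 0.1. A batch for each number within DEX stays open: the highest differently numbered pair (0.175) and the lowest same-numbered pair (0.171) differ by far less than the SD of 0.137 of the 18 correlations in the other treatments. A common handling of the arrays numbered 1 alone stays open too, and no biological explanation was tested.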
